A study of Mus musculus with 12 samples.

How the data were processed

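Gene expression was measured on 12 Affymetrix mouse arrays, 1 per RNA sample, from geniculate ganglia of mouse embryos at embryonic day 14.5. Per the labels, total RNA was extracted with a column kit and treated with DNase I, amplified, fragmented and biotinylated with the WT-Ovation Pico system, and hybridized. The 4 groups were wild type and BDNF knockout on the C57BL/6J background (the BDNF line) and wild type and NT4 knockout on the 129 background (the NT4 line), with 3 arrays per group that the labels call biological replicates. How many embryos went into each RNA sample is not given in the sources used here. Each line thus has its own strain and its own wild type, so strain and colony go with the line and cannot be separated between lines. Dates of processing are not given.

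The value table deposited by the authors gives 1 intensity per probe set and array for 45101 probe sets. The values were not whole, ran from 0.89 upwards and had array medians of 168 to 201, so they were read as linear intensities made by the authors. How background was handled and how arrays were scaled before the values were deposited is not given in the sources used here. The plan had assumed log2 values, so the log2 of each deposited intensity was taken, with no offset. In addition, the authors deposited 2 lists of probe sets chosen by them, 667 for BDNF and 672 for NT4, with linear mean intensities, standard errors, a signed linear fold change (a score that is positive where the knockout was higher and negative where it was lower) and an unadjusted p-value of the authors' t statistic, per the file headers. The array columns of these lists were identical to the value table. Every listed probe set met a fold of at least 1.2, a difference of means of at least 50 and an unadjusted p-value under 0.05, and applying these criteria to the value table gave the same 667 and 672 probe sets, so they are taken as the authors' criteria.

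After 64 array control probe sets were left out, 45037 probe sets were tested. The table of probe set names gave 1 gene symbol for 34945, several for 932 and none for 9160, and 34741 of the first matched the gene table of assembly GRCm38.p6, which was used only for names, chromosomes and the order of neighbouring genes. The probe sets with 1 symbol covered 18193 genes. Array data carry no counts, so the number of arrays limits the precision. The median standard error of a log2 change between 2 groups was 0.20.

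Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, residual degrees of freedom 8, prior degrees of freedom 2.27), and 4 contrasts were tested two-sided: each knockout against its own wild type, the difference of these 2 effects, and the 2 wild types against each other. P-values were adjusted by the Benjamini-Hochberg method over the 45037 probe sets of a contrast, with a threshold of 0.05. A gene is said to have risen, fallen or changed only where it passed this threshold, and a list that passed its test is called higher or lower. Log2 changes are given with limma's standard error (SE), intensities as mean ± SD of 3 arrays. The 2 knockout effects were also correlated across probe sets and compared with the 100 pairs of splits of the arrays within each line. A value per array was compared between 2 groups by an exact two-sided permutation test, which with 3 arrays against 3 cannot give a p under 0.1.

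The list tests used 32 gene lists with 618 members, of which 565 were measured. They cover types of sensory neuron, glia and surrounding tissues, neurotrophin and MAPK signalling, cell death and injury, axon guidance and growth, synapses and channels, cell cycle, ribosomes, metabolism, stress and interferon. Each gene was represented by its brightest probe set. Lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and beside it with camera at an estimated correlation and with fry, which tests whether the members move on balance in 1 direction and, in a second p-value, whether they change in either direction. Adjustment was over the 32 lists of a contrast. List members are also counted with p-values adjusted over the list alone.

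The named genes follow a rule. It takes Bdnf, Ntf5 (the gene for NT4), Ntrk2 and Ngfr, then up to 10 rises and 10 falls per knockout contrast among probe sets with 1 symbol that passed the threshold, did not overlap between groups and had the higher mean above the median. Free places were filled in order of unadjusted p, and such genes are named as not past the threshold. For the difference and the wild types 5 of each sign were taken, for each list described up to 4 members by unadjusted p, and from each list of the authors the 5 largest folds per direction. Probe sets without a single symbol that passed are named by their identifier. Neighbours of Bdnf and Ntf5 were examined after the calls had been seen.

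The contrasts, tests, gene lists and naming rule were chosen before the data were examined, as were these alternatives: a mean-variance trend with robust estimation, leaving out the dimmer 50% of probe sets, quantile normalization, centring of the arrays, array weights, the replicate number as a block, sex-linked expression as a covariate, 1 probe set per gene, an unadjusted threshold with a fold of 1.5, fitting only 6 arrays, 3 other list tests and leaving out each array. With the trend, camera used only its variance trend. Chosen after the data were seen were offsets of 16 and 50, leaving out both wild-type arrays with high Xist, the centring of list means and all alternatives for fry's test in either direction. The fits and the list tests were tested on simulated data, drawn with the mean and spread of each real probe set and with known changes added. The changes were added only to probe sets brighter than the median, 50 per size. Among these the BDNF contrast found 56% at a 2-fold change and 94% at a 4-fold change. The simulated BDNF contrast made 140 calls, which eases the adjusted threshold, so these shares may be too high for the real data.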

Results

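Expression was measured in geniculate ganglia, the cranial ganglia that hold the cell bodies of taste neurons, at embryonic day 14.5. There were 4 groups of 3 arrays: wild type and BDNF knockout of the BDNF line, and wild type and NT4 knockout of the NT4 line. Array medians lay between 168 and 201. On an array, 5.87% to 7.91% of probe sets had an intensity under 20. The log2 values of replicates correlated at r = 0.967 to 0.985. Knockout and wild-type arrays of 1 line correlated at 0.965 to 0.982, and arrays of different lines at 0.919 to 0.945. On any 2 arrays at most 0.0443% of the values were equal, so no array was a copy of another. The ratio of 3' to 5' signal, a sign of RNA integrity and labelling, was 2.10 to 2.55 for Gapdh and 0.90 to 1.0 for Actb. BDNF wild-type replicate 2 and NT4 wild-type replicate 2 stood apart in sex-linked genes. Their log2 Xist exceeded the mean of the Y-linked genes by 8.09 and 7.92, against 2.79 to 5.09 on the other arrays.

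The first comparison asked what the loss of BDNF, a neurotrophin that acts through the receptor encoded by Ntrk2, changed in the ganglion. Bdnf itself (1422168_a_at, chromosome 2) fell by 3.18 on the log2 scale (SE 0.25, adjusted p = 0.00177). Its intensity was 233 ± 60.0 (SD, n = 3) in the wild type and 25.1 ± 1.79 (SD, n = 3) in the knockout, and each knockout array lay under each wild-type array. Scg5, a chaperone of the enzymes that process prohormones, rose by 1.38 (1423150_at, SE 0.15, adjusted p = 0.0196), from 1712 ± 187 to 4442 ± 186. Pak6, a protein kinase, rose by 2.17 (1455200_at, SE 0.19, adjusted p = 0.00497), from 71.4 ± 11.9 to 323 ± 67.2, while its other probe set differed by −0.08. Bloc1s6, a subunit of a complex that sorts cargo to lysosome-related organelles, rose by 3.42 on 1 of its 3 probe sets (1457088_at, SE 0.18, adjusted p = 0.000117), from 103 ± 25.2 to 1090 ± 137. Its other probe sets differed by −0.09 and 0.71.

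Rmdn3, a protein at contacts between mitochondria and the endoplasmic reticulum, fell by 1.94 in the BDNF knockout (1428196_a_at, SE 0.21, adjusted p = 0.0196), from 1927 ± 104 to 519 ± 161 (SD, n = 3 each). Its other probe set differed by −0.38. Nr5a2, an orphan nuclear receptor of the group that binds DNA as a monomer, fell by 1.58 (1456521_at, SE 0.19, adjusted p = 0.0490), from 1265 ± 87.5 to 434 ± 118. The 3 Nr5a2 probe sets were lower too, by −1.32, −0.57 and −0.91. The other falls were −4.71 for 1446755_at (SE 0.35), which has no gene symbol, and −0.99 for 1442514_a_at (SE 0.11), which matches both Serinc4 and Ell3. Scg5, Pak6, Rmdn3 and Bloc1s6 lie on chromosome 2 like Bdnf, at 22, 47, 60 and 139 measured genes from Bdnf. Serinc4 and Ell3 lie between them, at 118 and 117, and Nr5a2 lies on chromosome 1. In both genotypes of the NT4 line the raised Bloc1s6 probe set read near the level of the BDNF knockout, at 1053 and 1113. The second Bdnf probe set (1422169_a_at) read 262 in the wild type and 315 in the knockout, a log2 change of 0.27 (adjusted p = 0.867). Since the sources do not give the deleted part of the gene, this probe set checks nothing. The receptor genes did not pass, with 0.24 for Ntrk2 and −0.26 for Ngfr. Among genes short of the threshold were the mitochondrial Cox15 (0.77) and the proton pump subunit Atp6v0a1 (0.94). Chromosome 2 held Ehd4 (0.80), Tmem87a (0.78), Pdia3 (−0.97), Ppip5k1 (−1.27), Mga (−1.75) and B2m (−1.14). Other chromosomes held Zfp800 (1.54), Tbc1d2b (1.18), Bcl2l12 (0.97), Matr3 (−1.12), Trpc1 (−0.70) and Ftx (−2.18). These genes had an adjusted p of 0.0765 to 0.229, each on 1 probe set. Of the 10 with other probe sets only B2m had one that went the same way at an unadjusted p under 0.05 (−0.55). At that threshold a probe set went the opposite way for Zfp800 (−0.71) and for Mga (0.30, its brightest). The brighter probe sets differed by 0.09, 0.10 and 0.05 for Matr3, 0.03, −0.00 and 0.02 for Atp6v0a1, and 0.05 for Pdia3. The others of Cox15 differed by −0.05, −0.01 and −0.46. Ehd4, Ftx, Tbc1d2b and Tmem87a have a single probe set.

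In all, 8 probe sets changed with the loss of BDNF, 3 upwards and 5 downwards. Some 3025 had an unadjusted p under 0.05 where chance gives 2252. The count was 5 without BDNF wild-type replicate 1, 2 or 3 or NT4 wild-type replicate 3, 4 without NT4 wild-type replicate 1 or 2, and 4 without both arrays of high Xist. A limma fit of only the 6 arrays of the line made 0 calls (2465 at an unadjusted p under 0.05). Bdnf, Bloc1s6, Pak6 and 1446755_at stayed past the threshold in each of the fits with 1 array left out, and Pak6 was lost without both arrays of high Xist. Quantile normalization called 5 upwards and 5 downwards.

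In the BDNF knockout, gene lists for somatosensory neurons, feedback on MAPK signalling, semaphorins, and Slits, Robos and netrins differed from no change. This was by fry's test in either direction, with members on both sides. The guidance list of ephrins and Eph receptors did not pass that test (adjusted p = 0.120). In the somatosensory list Avil, an actin regulator of sensory neurons, differed by −0.48 (SE 0.13), and the transcription factors Prrxl1 and Pou4f1 by −0.61 (SE 0.18) and −0.47 (SE 0.14). Trpv1, the heat and capsaicin receptor gene, differed by 1.93 (SE 0.49), from a dim 17.6 to 76.0 (n = 3 each), so only its direction is read. Avil read 2582 in the wild type and 1846 in the knockout, and Pou4f1 4777 and 3484. Of the 12 measured members 0 passed over all genes, while 1 rose and 3 fell adjusted over the list alone. The MAPK feedback list was lower on each of the 3 knockout arrays than on any wild-type array of the line (exact two-sided permutation p = 0.1, the smallest possible), with a mean of −0.23 over 15 members. Adjusted over the list alone 2 members fell. Etv4, an ETS factor induced by receptor tyrosine kinases, fell by 1.70 (SE 0.41; 424 to 131), and Spred3, a Ras-MAPK inhibitor, fell by 0.60 (SE 0.17). Next came Dusp6, an ERK phosphatase, at −0.40 and Phlda1 at 0.41.

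Of the 31 genes for semaphorins and their receptors, Plxnc1 fell adjusted over the list alone (−0.63, SE 0.12; 1328 to 857, n = 3 each). Plxnb2, Sema3d and Plxna2 were higher by 0.51, 0.45 and 0.35 without passing. In the list of Slits, Robos, netrins and related guidance genes Flrt3 (0.38), Unc5a (0.70), Cntn2 (−0.43) and Slit1 (−0.55) stood first. By limma 0 of 30 passed over all genes or over the list alone. Fry's test in either direction gave an adjusted p of 8.29e-05 for the somatosensory, 0.000715 for the MAPK feedback, 0.00134 for the Slit and 0.00885 for the semaphorin list. This test does not set a list against other genes. Camera, which does, passed 0 of 32 lists (4 at an unadjusted p under 0.05). Its lowest adjusted p was 0.0608, for hypoxia and glycolysis at a mean of 0.14 (Egln3 0.75, Aldoc 0.23), and it was 0.925 with an estimated correlation. For MAPK feedback the values were 0.101 and adjusted p = 0.779 with an estimated correlation. Camera with an estimated correlation and fry's test of 1 shared direction also passed 0 lists (1 each at an unadjusted p under 0.05). Over all genes 0 of the 565 measured members passed limma's threshold (19 higher and 20 lower at an unadjusted p under 0.05). The somatosensory list passed in either direction with each array left out. Without both arrays of high Xist it alone passed, and the MAPK feedback (adjusted p = 0.171), semaphorin (0.558) and Slit lists (0.0555) were lost. The MAPK feedback list was also lost without BDNF wild-type replicate 2 (adjusted p = 0.057) or 3 (0.135). The semaphorin list was lost without BDNF wild-type replicate 2 (0.293) or BDNF knockout replicate 1 (0.198) or 3 (0.242), and the Slit list without BDNF knockout replicate 1 (0.0672) or 3 (0.242).

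**Figure D1:**
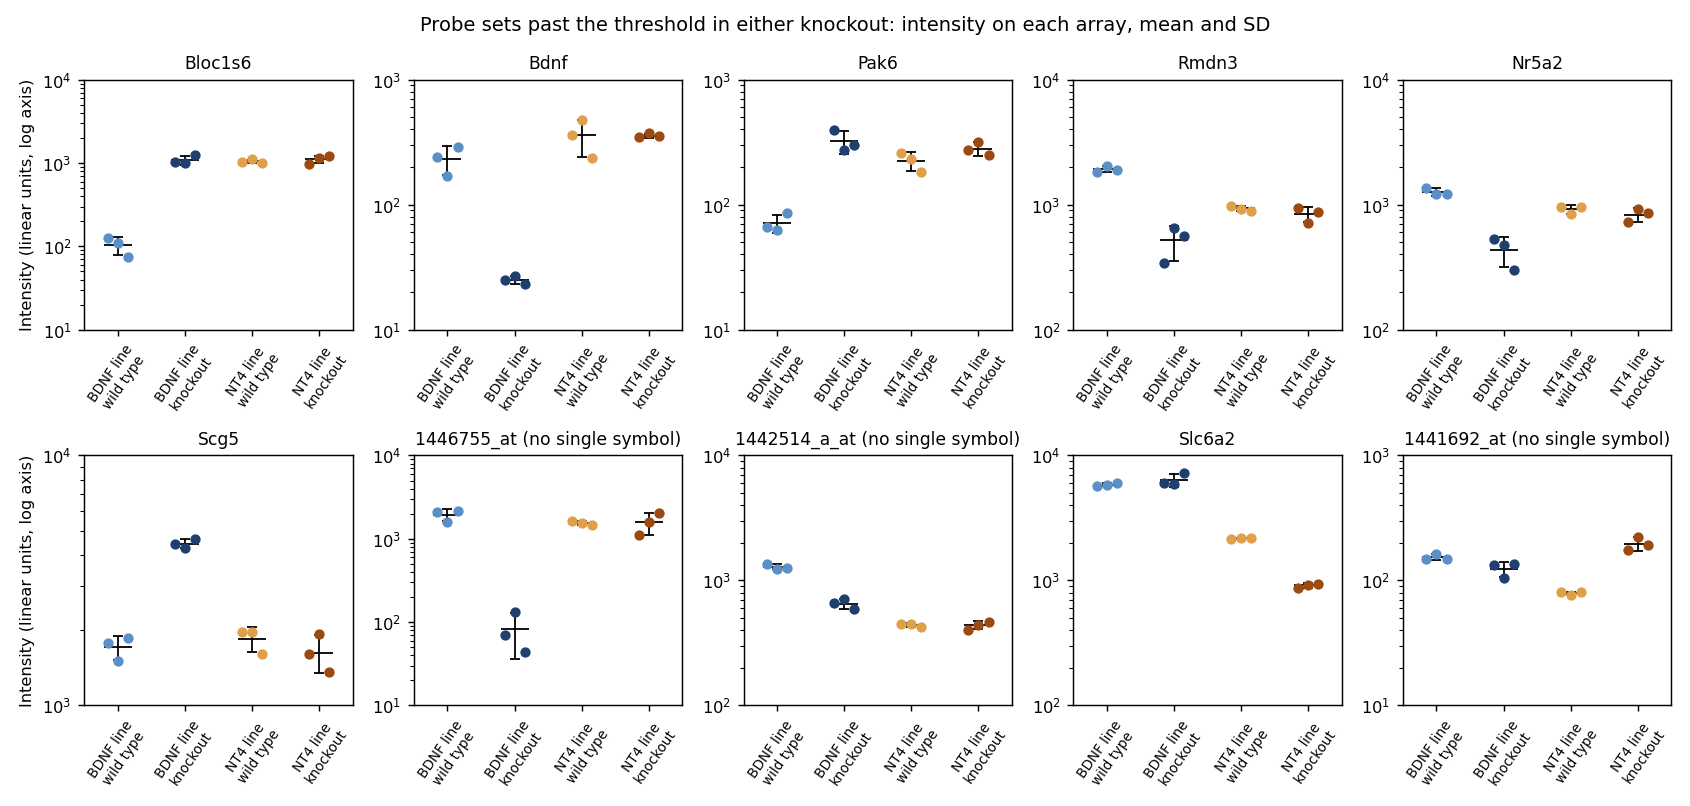
Intensity (linear units, log axis) on each array (points) of the 10 probe sets called in either knockout comparison, in 4 groups of 3 arrays, with bars for the group mean and SD. Bdnf dropped from 233 to 25.1 in the BDNF knockout, the Bloc1s6 probe set was near 1090 in every group except the BDNF wild type (103), and Slc6a2 read 2172 in the NT4 wild type and 911 in the NT4 knockout.

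The second comparison asked what the loss of NT4, the other neurotrophin that binds the same receptor, changed. Ntf5, the gene for NT4 (1440353_at, chromosome 7), was dim in both genotypes, at 41.1 ± 6.56 in the wild type and 38.6 ± 3.29 in the knockout (SD, n = 3 each). Its log2 change was −0.08 (SE 0.16), so its level cannot check the genotype labels. Slc6a2, the noradrenaline transporter (1442449_at, chromosome 8), fell by 1.25 (SE 0.11, adjusted p = 0.0113), from 2172 ± 24.9 to 911 ± 41.4. It was lower in 3 of 3 knockout arrays than in any wild-type array. A second bright Slc6a2 probe set (1460129_at) differed by −1.36 without passing (adjusted p = 0.375), and the other two by −1.27 and 0.23. In the BDNF line the called probe set read 5837 and 6389. The only other call was the rise of 1441692_at, which has no symbol, by 1.31 (SE 0.13, adjusted p = 0.0316), from 79.2 ± 1.87 to 197 ± 24.8.

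Ntrk2 and Ngfr did not pass in the NT4 knockout (0.50 and −0.06). Nor did the genes next in order, at adjusted p of 0.375 to 0.790. On the upper side were the macrophage genes Csf1r (1.08 on 1419873_s_at) and Tyrobp (1.24), the membrane glycoprotein Gpm6b (1.28), the recombination factor Rad51ap1 (0.74), the neuropeptide gene Cort (0.71), Foxd1 (0.76), Dnttip1 (1.96), Myo5b (0.58), Phf3 (0.70) and Nip7 (0.62). On the lower side were the synaptic scaffold gene Lin7b (−1.07), the GABA receptor subunit Gabrg1 (−0.71), Pcdh10 (−0.78), Racgap1 (−0.52), Anks1b (−0.63), Diras2 (−0.58), Klk1b24 (−0.69), B3galt1 (−0.52) and Lancl3 (−0.55). Of the 14 of these genes with other probe sets, 5 (Csf1r, Gabrg1, Lin7b, Pcdh10 and Phf3) had one that went the same way at an unadjusted p under 0.05. For the other 9 none did, as for Gpm6b (−0.01 and 0.00) and Dnttip1 (0.06). In all, 2 of 45037 probe sets changed, 1 upwards and 1 downwards, with 2530 at an unadjusted p under 0.05 against 2252 by chance. With centred arrays the median log2 change of all probe sets moved from 0.05 to −0.07 and the count was 0 upwards and 1 downwards. Limma made 0 calls without NT4 knockout replicate 2 or 3, NT4 wild-type replicate 1 or 2, both arrays of high Xist, or the BDNF line (1532 to 2972 at an unadjusted p under 0.05). There was 1 call without NT4 wild-type replicate 3, BDNF knockout replicate 1 or 3 or BDNF wild-type replicate 1, 2 or 3, and there were 5 without NT4 knockout replicate 1.

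In the NT4 knockout, lists of genes for cartilage, macrophages, the cell cycle, connective tissue and inner ear epithelium were higher on balance, set against all other genes. That is by camera at its preset correlation. On list means per array, the exact two-sided permutation p was 0.1, the smallest possible, for cartilage, macrophage and inner ear genes. It was 0.2 for the cell cycle and 0.5 for connective tissue. Cartilage genes were higher by a mean of 0.59 (16 of 16 members higher; camera adjusted p = 4.05e-05, adjusted p = 0.751 with an estimated correlation). Acan, the cartilage proteoglycan, stood at 1.28 (SE 0.66), the master regulator Sox9 at 0.69 (SE 0.27), Matn4 at 0.66 and Snorc at 0.52. Macrophage genes were higher by 0.57 (13 of 15 higher; camera adjusted p = 6.82e-05, adjusted p = 0.440 with an estimated correlation). Adjusted over the list alone 2 of them rose, Csf1r, the receptor for macrophage growth factor, by 1.36 on its brightest probe set (1419872_at, SE 0.35; 421 to 1071, n = 3 each), and Tyrobp, a microglial and macrophage adaptor, by 1.24 (SE 0.26; 495 to 1180). The complement gene C1qb (0.97) and Aif1 (0.74) came next. Csf1r was also higher by 1.38 on that probe set in the BDNF knockout, where it passed adjusted over the list alone while the list's mean of 0.26 did not (camera adjusted p = 0.303). Another probe set (1423593_a_at) differed by 0.34 in the NT4 and −0.05 in the BDNF knockout. Cell cycle genes were higher by 0.26 (25 of 25 higher; camera adjusted p = 8.97e-05, adjusted p = 0.751 with an estimated correlation). Among them were Cdc20 (0.63), Mcm3 (0.49), Ccna2 (0.46) and Ccnb2 (0.41). Connective tissue genes were higher by 0.35 (17 of 18 higher; 0.00175, adjusted p = 0.962 with an estimated correlation). Col1a1 stood at 0.35, Fbln1 at 0.28, Pdgfrb at 0.38 and Col5a1 at 0.40. Inner ear genes were higher by 0.33 (10 of 12 higher; 0.0223, adjusted p = 0.440 with an estimated correlation). Lmx1a stood at 1.06, from a dim 9.61 to 22.1, so only its direction is read. Oc90 stood at 0.40 and Otoa at 0.36.

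Genes of the mitochondrial respiratory chain had a mean of −0.09 in the NT4 knockout (32 of 33 lower; camera adjusted p = 7.70e-05, adjusted p = 0.751 with an estimated correlation), with Cox5a at −0.16 and Uqcrq at −0.25. Heat shock genes had a mean of −0.12 (14 of 19 lower; 0.0229, adjusted p = 0.751 with an estimated correlation; Herpud1 −0.41, Hspb1 −0.48). For genes of cholesterol synthesis the mean was −0.07 (12 of 16 lower; 0.0229, adjusted p = 0.751 with an estimated correlation). There the cholesterol carrier gene Stard4 fell adjusted over the list alone (−0.40, SE 0.09) and Mvd stood at −0.21. Pan-neuronal genes had a mean of −0.06 (12 of 18 lower; 0.0495, adjusted p = 0.962 with an estimated correlation; Nefh −0.40). With an estimated correlation and by fry's test of 1 direction 0 lists passed (2 and 3 at an unadjusted p under 0.05). Fry's test in either direction passed 1, cholesterol synthesis (adjusted p = 0.00643). That call was lost without NT4 wild-type replicate 2 (0.424), NT4 knockout replicate 2 (0.220) or 3 (0.0810), BDNF wild-type replicate 1 (0.0517), 2 (0.0763) or 3 (0.108), or both arrays of high Xist (0.811). Over all genes 0 of 565 list members passed limma's threshold (21 higher and 7 lower at an unadjusted p under 0.05). On list means per array, the exact two-sided permutation p was 0.2 for the respiratory chain and 0.3 for heat shock. It was 0.3 for cholesterol synthesis and 0.4 for pan-neuronal genes.

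The sizes of these list means depend on single arrays and on scaling. Without NT4 knockout replicate 1, the array of the NT4 line with the most cartilage signal, camera passed 4 lists in place of 9. The cartilage mean was then 0.36 (adjusted p = 0.108), cell cycle 0.15 (0.327), connective tissue 0.19 (0.417), inner ear 0.32 (0.123), cholesterol −0.06 (0.108) and pan-neuronal −0.01 (0.918), and heat shock moved to −0.19. Without NT4 wild-type replicate 2 camera passed 5, with connective tissue at 0.14 (0.340), heat shock at −0.10 (0.248), cholesterol at −0.03 (0.340) and pan-neuronal genes at −0.06 (0.248). Connective tissue stood at 0.22 (0.130) without NT4 wild-type replicate 1 and at 0.71 without NT4 wild-type replicate 3. The inner ear call was also lost without NT4 wild-type replicate 3 (0.0702) or NT4 knockout replicate 2 (0.0883). Heat shock was lost without NT4 knockout replicate 2 (0.116) or 3 (mean −0.05, 0.373) and cholesterol without NT4 knockout replicate 3 (mean −0.04, 0.128). Without NT4 knockout replicate 2 the cholesterol and pan-neuronal means were −0.10 each, and without NT4 knockout replicate 3 the respiratory chain stood at −0.06. Pan-neuronal genes were lost too without NT4 wild-type replicate 1 (0.341), BDNF wild-type replicate 1 or 3 or BDNF knockout replicate 1, 2 or 3 (0.0523 to 0.0596). Macrophage genes passed in each of 15 other settings, and the respiratory chain in all but quantile normalization (0.0655). All of these settings kept camera's preset correlation, and some left out only a BDNF-line array. With an estimated correlation neither list passed. With centred arrays all 9 passed, but the means moved to −0.21 for the respiratory chain, −0.24 for heat shock, −0.18 for cholesterol, −0.18 for pan-neuronal genes, 0.15 for the cell cycle, 0.21 for inner ear, 0.24 for connective tissue, 0.47 for cartilage and 0.46 for macrophages. Axon growth genes (−0.12, camera adjusted p = 0.00819) and ribosomal protein genes (−0.16, 0.0274) passed then as well.

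**Figure D2:**
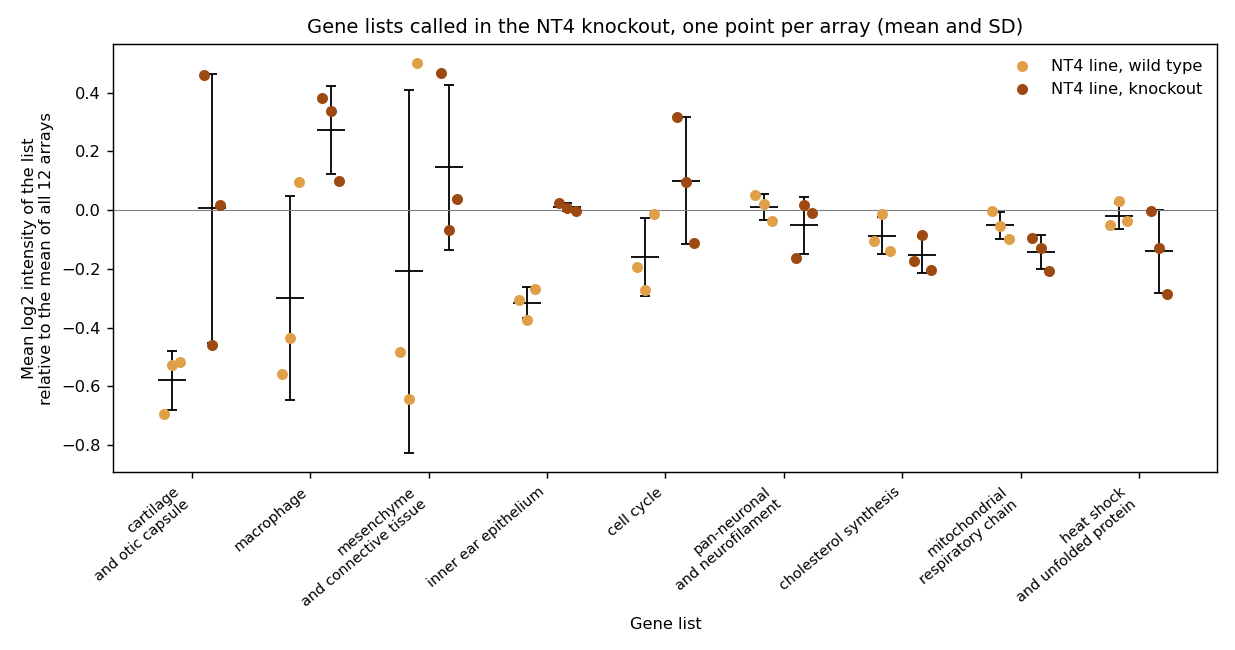
Mean log2 intensity of the 9 gene lists called in the NT4 knockout on each array of the NT4 line (points, 3 wild-type and 3 knockout arrays), relative to the mean of all 12 arrays, with bars for the group mean and SD. For cartilage the knockout arrays stood at 0.46, −0.46 and 0.02 against −0.69, −0.53 and −0.52 in the wild type, while pan-neuronal values of both genotypes overlapped.

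The remaining lists bear on cell identity, cell death and growth, and on all 12 arrays as deposited, at default settings, none of them passed in either knockout by camera or by fry's test in either direction. Genes for visceral and gustatory sensory neurons had mean changes of 0.06 with the loss of BDNF (P2rx2 0.26, Gfra2 0.30) and −0.02 with the loss of NT4. In the same order the means were −0.33 and 0.00 for cochleovestibular neuron genes and 0.08 and 0.04 for genes of Schwann cells and satellite glia. Apoptosis genes had means of 0.01 (Hrk 0.39) and 0.08 (Bcl2l11 0.38, Casp8 0.51). The means were −0.11 and 0.05 for p53 targets, −0.03 and 0.02 for injury-induced transcription factors and peptides, and −0.05 and 0.08 for immediate early genes. The neurotrophin list stood at 0.06 (Ntrk3 0.88, Gdnf −0.91) and 0.10 (Sort1 0.60), and ephrins at 0.04 and 0.02. Axon growth genes stood at −0.00 and −0.01 (−0.12 with centred arrays, where camera passed them), synaptic genes at −0.05 and 0.02, and ion channels at −0.12 and −0.02. Endothelial genes had means of 0.08 and 0.07, skeletal muscle 0.04 and 0.13, and erythroid −0.01 and 0.06. Ribosomal protein genes had 0.04 and −0.04 (−0.16 with centred arrays, where camera passed them), interferon response genes −0.04 and 0.06 and sex-linked genes 0.86 and 0.94. The sex-linked means rest on the 2 wild-type arrays of high Xist and were −0.03 and 0.01 without them. For lists that passed in the other knockout, the loss of BDNF gave 0.17 for cartilage, 0.12 for connective tissue, 0.11 for inner ear and −0.08 for the cell cycle. It gave 0.02 for the respiratory chain, 0.04 for heat shock, −0.03 for cholesterol synthesis and −0.01 for pan-neuronal genes. The loss of NT4 gave 0.05 for the somatosensory, −0.04 for the MAPK feedback, 0.09 for the semaphorin and 0.07 for the Slit list. The hypoxia list, which passed in neither on all 12 arrays as deposited at default settings, stood at 0.06 with the loss of NT4. With centred or quantile-normalized arrays many of these means in the NT4 knockout changed sign, apoptosis to −0.03 among them. No direction is read from any of these means.

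The third comparison asked whether the effects of the knockouts differed, by testing the BDNF effect minus the NT4 effect. The genes that set the knockouts apart were Bloc1s6 (3.35, SE 0.26, adjusted p = 0.00450) and Slc6a2 (1.38, SE 0.15, adjusted p = 0.0306) upwards. Downwards they were Bdnf (−3.23, SE 0.35, adjusted p = 0.0306), 1446755_at (−4.69, SE 0.50, adjusted p = 0.0306) and 1441692_at (−1.63, SE 0.19, adjusted p = 0.0413). Bdnf was targeted in 1 line only, so its difference was set by the design. On the Bloc1s6 probe set the wild types already differed by 3.38, near its change of 3.42 in the BDNF knockout. Its difference is therefore not read as a differing response to the 2 losses. Pak6 (1.85), Scg5 (1.57) and Anks1b (1.16) on the upper side and Matr3 (−1.94), Rmdn3 (−1.79), Gpm6b (−1.70) and Myo5b (−0.89) on the lower side did not pass. Of these 7 genes Scg5 has a single probe set, and no other probe set of the rest went the same way at an unadjusted p under 0.05 (Matr3 0.17, 0.08 and 0.20), while 1 for Anks1b went the opposite way (−2.50). The calls of Pak6, Scg5 and Rmdn3 in the BDNF knockout are thus not shown to differ from the NT4 knockout. Cell cycle genes differed downwards by a mean of −0.34 (25 of 25 members; camera adjusted p = 0.00461; Bub1b −1.25, Cdc20 −0.78). Respiratory chain genes differed upwards by 0.11 (30 of 33; 0.00218; Ndufs1 0.36, Cox7c 1.25). For both the adjusted p was 0.895 with an estimated correlation. The differences of the somatosensory and MAPK feedback lists did not pass (fry in either direction, adjusted p = 0.0595 and 0.923), nor did those of the cartilage (−0.42, camera adjusted p = 0.204) and macrophage lists (−0.31, 0.175). With the arrays centred, the median log2 difference of all probe sets moved from −0.07 to 0.06. Then 9 lists passed, cartilage (−0.29) and macrophage (−0.19) among them, with the cell cycle at −0.21 and the respiratory chain at 0.24.

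Of 45037 probe sets 5 passed, 2 upwards and 3 downwards (2632 at an unadjusted p under 0.05), against 2 and 1 with centred arrays and 3 and 1 after quantile normalization. The count was 1 without BDNF wild-type replicate 1 or 3, BDNF knockout replicate 1, NT4 wild-type replicate 1, NT4 knockout replicate 2 or 3 or both arrays of high Xist. It was 2 without BDNF wild-type replicate 2, BDNF knockout replicate 2 or 3 or NT4 wild-type replicate 2, and 3 without NT4 wild-type replicate 3. The cell cycle call was lost without BDNF wild-type replicate 2 (adjusted p = 0.101), BDNF knockout replicate 1 (0.0760), NT4 knockout replicate 1 (0.428) or both arrays of high Xist (mean −0.19, 0.328). The respiratory chain call was lost without NT4 knockout replicate 3 (0.101) or with quantile normalization (0.159). Camera passed 4 lists without BDNF knockout replicate 2 or NT4 knockout replicate 1, and 5 without BDNF knockout replicate 3. It passed 6 without BDNF wild-type replicate 2 or NT4 wild-type replicate 3 and 1 without NT4 knockout replicate 3. Across probe sets, which are not independent replicates, the knockout effects correlated at r = 0.044 (48 of 100 pairs of splits within lines gave a larger or equal size, permutation p = 0.48). Spearman's rho was 0.043 (permutation p = 0.57), each with an adjusted p of 0.57 over these 2 measures. Without BDNF wild-type replicate 1 r was −0.00528, and without BDNF wild-type replicate 2 it was 0.120. The calls of the knockouts shared 0 probe sets, where 0.000355 would be shared by chance.

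**Figure D3:**
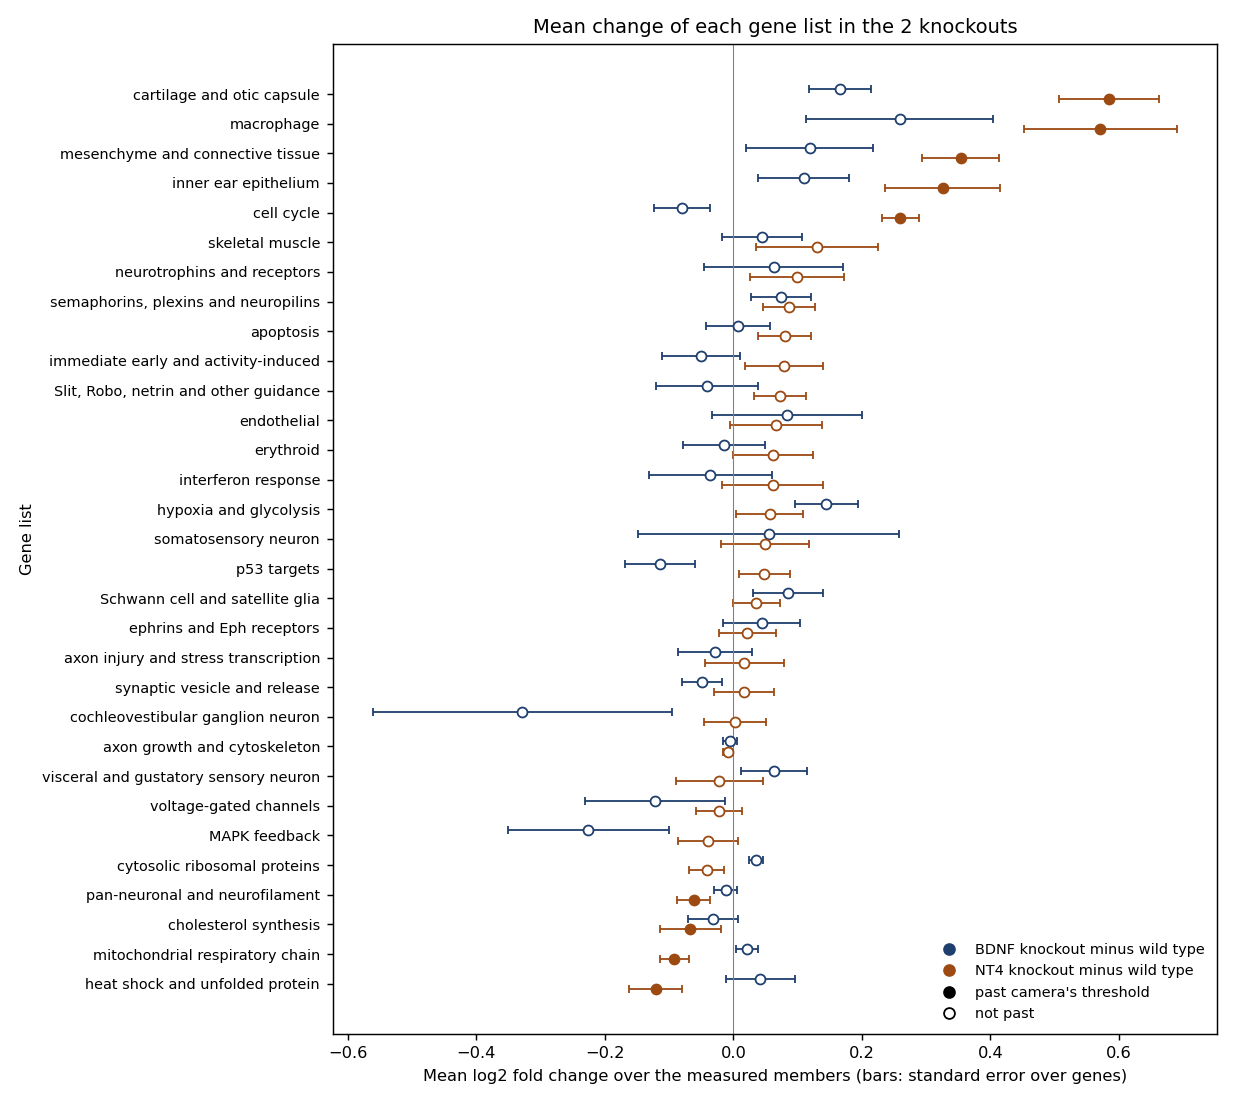
Mean log2 change of 31 gene lists (the sex-linked list is not drawn) in the BDNF and the NT4 knockout, each against its own wild type, with bars for the standard error over member genes and filled points for lists past camera's threshold. In the NT4 knockout 9 lists passed, from cartilage at 0.59 to heat shock at −0.12, and in the BDNF knockout 0 of 32 did (4 at an unadjusted p under 0.05).

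The authors' deposited table for BDNF lists 667 probe sets, 284 higher and 383 lower in the knockout. The authors' deposited table for NT4 lists 377 higher and 295 lower. At the top of the authors' deposited table for BDNF stand Bloc1s6 (10.56-fold), Aff4 (5.44), Pak6 (4.53), the potassium channel gene Kcnk6 (3.59) and Zfp800 (2.92) among the higher. Among the lower stand Bdnf (−9.28), Rmdn3 (−3.71), Mga (−3.26), the integrin gene Itgb1 (−3.10) and Car3 (−2.99). At the top of the authors' deposited table for NT4 stand Lgr5 (3.70-fold), the cardiac and hindbrain factor Tbx20 (2.95), Gigyf2 (2.85), the immune genes Ly86 (2.79) and Csf1r (2.55) among the higher. Erich6 (−3.19), Slc6a2 (−2.50), Gabrg1 (−2.49), the endothelin-converting enzyme Ece2 (−2.41) and Reg3b (−2.13) stand among the lower. The 8 and 2 probe sets called by limma are all in the authors' deposited table of their comparison. For BDNF and NT4, 557 and 450 of the listed probe sets had an unadjusted limma p under 0.05. When the p-values in the authors' deposited table were adjusted over all probe sets, the lowest were 0.869 and 0.466. Both of the authors' deposited tables list 24 probe sets, where 12.4 are expected by chance among 35431 bright enough to enter (odds ratio 2.02, 95% interval 1.27 to 3.05, two-sided Fisher's exact p = 0.00205). Fisher's test counts probe sets as independent replicates, which they are not, so no shared effect is read from this excess. Of the 24 shared probe sets, 6 were higher in both knockouts, 7 lower in both, and 5 and 6 in opposite directions. No pairing of directions passed by itself (adjusted p of 0.114 to 0.298 by Fisher's exact test).

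The last comparison, of the NT4-line wild type with the BDNF-line wild type, gives the background against which each line was measured. The lines differed at 6275 probe sets, 2918 higher and 3357 lower in the NT4 line, with a change of at least 2-fold at 4127 and an unadjusted p under 0.05 at 11224. The largest differences were −10.59 for the kinesin gene Kif5c, −9.95 for the autophagy gene Atg12, −9.64 for Aplp2, −8.62 for Marcks and −8.46 for Zfand3. Upwards they were 8.52 for the collagen receptor gene Ddr1, 7.18 for Tm2d2, 5.57 for Pappa, 5.31 for Apbb1 and 5.26 for Ikbkg. All but Tm2d2 (22.5) and Apbb1 (160) had a dimmer side under 20, as Kif5c with 5036 against 4.68, so near the floor of the array their sizes and order depend on background. The other probe sets of these genes mostly did not follow: those for Kif5c differed by 0.10, −0.11 and −0.11. Among those that passed, 1 for Zfand3 was lower too (−0.63), while 1 each for Marcks (1.86), Tm2d2 (−0.93) and Ddr1 (−0.58) went the other way. Bloc1s6 (3.38) and Pak6 (1.66), which rose in the BDNF knockout, were higher in the NT4 line on the same probe sets, and Rmdn3 (−1.05), which fell, was lower. Ntf5, with 1 probe set, was lower in the NT4 line by −1.61. Slc6a2 was lower by −1.43, with −1.32, −1.43 and −1.17 on its other probe sets, and Ntrk2 by −0.55 (adjusted p = 0.0403) on 1 probe set.

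Among sensory neuron and developmental genes, 1 probe set each was lower in the NT4-line wild type for the neurogenic factor Neurod1 (−2.89), the guidance gene Flrt2 (−2.86) and the synaptic gene Rims1 (−2.33). Their other probe sets did not follow, with 0.17 for Neurod1, −0.18 and 0.18 for Flrt2 and 0.02 for Rims1, so these values are not read as levels of the whole gene. For genes with a single probe set this cannot be checked. They were the inner ear factor Lmx1a (−2.98), the synaptic Unc13a (−1.52), the stress factor Atf5 (−2.12), the interferon-induced Oasl2 (−2.56) and Oas1a (−1.28), Gadd45a (1.59) and Tecta (1.34). Lmx1a read under 20 in the NT4-line wild type, so only its direction is read. The Gadd45a call was lost in 8 of 25 alternatives (limma adjusted p up to 0.123). For Ntn4 both probe sets were higher (1.06 and 1.01). Of 565 list members, each by its brightest probe set, 17 were higher and 47 lower over all genes. By fry's test of 1 direction 8 lists passed towards lower values in the NT4 line, with cochleovestibular neuron genes first (mean −0.42, 6 of 10 members lower, adjusted p = 0.000574). Then came inner ear (8 of 12 lower), Slit and Robo (21 of 30), cholesterol synthesis (12 of 16), interferon (12 of 16) and axon injury genes (0.0141 each), the respiratory chain (26 of 33, 0.0427) and synaptic genes (17 of 24, 0.0473). The axon injury list had 8 members higher and 8 lower, a mean of −0.10 and a median of 0.02, so it was not lower as a whole. The cochleovestibular, Slit and synaptic lists hold Neurod1, Flrt2 and Rims1 by the same probe sets that the others did not follow. Their means rest in part on these values and are not read as levels of whole genes either. Set against other genes by camera, 0 of 32 lists passed (lowest adjusted p 0.264, 4 at an unadjusted p under 0.05) and 0 with an estimated correlation (0 unadjusted). By fry 24 passed in either direction. Camera passed 1 list without BDNF wild-type replicate 2. Strain, colony and any separate processing go with the line in this comparison and cannot be told apart.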

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

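Chosen only after the result was seen were the tests of where the called genes lie, of the uncalled genes beside Bdnf, of splits that keep the grouping of 1 line, of the share of neurons, of separate labelling and of dim probe sets, the comparison of other probe sets for calls under 4-fold, the permutation scheme and the centring for the cartilage lists and the splits for fry's test in either direction.

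The test of the difference between the knockout effects set apart 5 probe sets, Bloc1s6 (3.35), Slc6a2 (1.38), Bdnf (−3.23), 1441692_at (−1.63) and 1446755_at (−4.69). It also set apart the mean of the cell cycle genes (−0.34) and of the respiratory chain genes (0.11), all as the log2 BDNF effect minus the NT4 effect. From all pairs of splits of the arrays within each line 100 were drawn, and 3, the real one included, gave 5 or more probe sets (highest other 5). This share argues against chance only for a grouping of both lines at once. The real count includes the targeted Bdnf, which favours any pair that keeps the BDNF grouping. Chance is therefore not excluded for a difference between the knockouts. Both other pairs with a count of 5 kept the real BDNF grouping and mixed the NT4 arrays. Of all 20 pairs that keep the BDNF grouping 3 gave 5 or more (highest other 5), and of the 20 that keep the NT4 grouping 1 did (highest other 4), where 20 are too few for a share under 0.05. A count as large was thus reached with the NT4 arrays mixed, so its size alone does not show an NT4 effect beyond chance, although 2 of the 5 probe sets, Slc6a2 and 1441692_at, are those called in the NT4 knockout. For the lists called by camera 65 of 100 gave 2 or more (highest other 13), so chance cannot be excluded there. In these groups of 3, no array was tested for its distance from its own group.

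Signal outside the comparisons came from control probe sets for Bacillus transcripts, which can be added to RNA before labelling. Of 5 families 4 were brighter on each of the 6 NT4-line arrays than on any of the 6 BDNF-line arrays, dap by 1.81-fold, lys by 7.99-fold, phe by 5.62-fold and thr by 1.34-fold (exact two-sided permutation p = 0.00216 each, the smallest that 6 arrays against 6 can give). For lys only the direction is read, since at 15.5 on the BDNF-line arrays it lay under 20, near the floor. The remaining family, trp, was dim on both, at 20.6 and 15.5, and did not separate the lines. The hybridization controls differed by at most 0.05 on the log2 scale and did not separate the lines.

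In the BDNF knockout, 5 genes other than Bdnf were called. Of these, 4 (Scg5, Pak6, Rmdn3 and Bloc1s6) were among the 200 measured genes on each side of Bdnf. Only 1 called gene lay elsewhere, so no window elsewhere could hold more than 1, and no p-value is read from this comparison. The count of 4 is the pattern itself and supports no explanation of it. For the other measures, 10000 windows of 400 genes were drawn at random from 18021 genes, so they overlap. Their permutation p-values are shares of these windows, with no labels permuted. They rank the Bdnf window and are finer than the far fewer separate windows could give. Loss of BDNF acting on genes wherever they lie, as the whole cause, was argued against by the 396 genes of the window that were not called: their median absolute moderated t was 1.13, against a median of 1.01 and a 95th percentile of 1.08 elsewhere (one-sided permutation p = 0.0074). Nr5a2 was the only call elsewhere. A chromosome segment of another strain, carried with the targeted allele, may account for the cluster. Of the 102 genes of the window that differ between the wild types, 65.7% moved in the direction of that difference. Elsewhere the median was 55.6% and the 95th percentile 64.6% (one-sided permutation p = 0.0371). The 102 genes include the called Bloc1s6, Pak6 and Rmdn3, which moved in that direction and are part of the cluster itself. The share was not computed without them, and it lies close to the 95th percentile. Scg5 stands apart from this direction, since the wild types differed in it by only 0.11, and the sources do not give the strain in which the allele was made. The segment therefore stays open beside a local effect of the targeted change on its neighbours, which was not tested.

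In the NT4 knockout the cartilage (0.59), macrophage (0.57), connective tissue (0.35) and cell cycle (0.26) lists were higher by camera at its preset correlation. Without NT4 knockout replicate 1 the cartilage (0.36), connective tissue (0.19) and cell cycle (0.15) lists no longer passed, and connective tissue (0.22 and 0.14) did not without NT4 wild-type replicate 1 or 2 either and stood at 0.71 without replicate 3. A lower share of neurons, with every other cell type higher alike, was argued against over member genes, since the means of 7 non-neuronal lists spanned 0.55. Cartilage and macrophage genes lay above endothelial and glial genes by at least 3.63 standard errors over genes. These do not measure the spread between arrays, where the cartilage list had an SD of 0.46 in the NT4 knockout. A lower share of neurons with other cell types higher unequally was not tested. Carry-over of cartilage-bearing tissue in some dissections may contribute. After removal of group means, the cartilage and connective tissue lists moved together over 12 arrays (r = 0.583, rho = 0.622, exact two-sided permutation p = 0.0255 and 0.0162). Without the 2 arrays farthest from the median r was 0.427, so the relation rests in part on those. No other pair of lists was tested, so the relation is not shown to be particular to cartilage-bearing tissue. Whether cartilage genes were higher with the loss of NT4 in every knockout array depends on scaling: the lowest knockout array exceeded the highest wild-type array by 0.058 as deposited and lay 0.074 under it with centred arrays. The abundant cartilage collagen Col2a1 read 6002 and 8205 and the connective tissue list overlapped between genotypes. Carry-over and a change in the tissue itself both stay open.

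Between the wild types 6275 probe sets differed, and in 1014 genes a probe set differed at least 4-fold. A difference in expression of the whole gene was argued against for these, since in 6.06% of the 429 genes with another bright probe set that probe set followed (26 in the same and 22 in the opposite direction, median size 0.17 against 2.65), and under 4-fold 99 of 1464 followed and 32 went the other way. A general brightening of dim probe sets was argued against, since mouse probe sets as dim as the 4 control families shifted by a median of 0.094 and the families by 1.67. Single dim mouse probe sets spread widely, with a 95th percentile of 1.54. That is above the shifts of dap (0.85) and thr (0.42) and under those of phe and lys. Labelling or amplification done separately for the lines is consistent with the 4 control families, dap, lys, phe and thr, that separate them, while the dim trp did not. It stays open beside strain variants under the probes, which were not tested, and line, strain and any such batch cannot be told apart.

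For the comparisons of 3 arrays with 3 the 10 splits are too few for a share under 0.05. The real counts of probe sets were 8 for BDNF (highest other 2), 2 for NT4 (highest other 2) and 6275 for the wild types (highest other 0 by limma). Lists called by camera numbered 9 in the NT4 knockout (highest other 10), 0 in the BDNF knockout (highest other 7) and 0 between the wild types (highest other 5), with 4 and 4 at an unadjusted p under 0.05 for the last 2. Lists that passed in either direction by fry numbered 4 for BDNF (highest other 2), 1 for NT4 (highest other 5) and 24 for the wild types (highest other 2). By the authors' criteria the BDNF line gave 667 (highest other 726) and the NT4 line 377 higher and 295 lower (highest other 962 in all).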

How the results depend on the processing

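Chosen only after the data were seen were the tests with offsets of 16 and 50, without both wild-type arrays of high Xist, with centred list means, and all alternatives for fry's test in either direction. The cause of a change was not tested, except that fewer probe sets, fewer arrays or another threshold change a count by construction.

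Calls in the BDNF knockout held as follows. Bloc1s6 passed in 22 of 24 alternatives, 1446755_at in 22 of 24 and Bdnf in 21 of 23, each lost only with the replicate block and with the 6 arrays of the line alone. Pak6 passed in 22 of 25, Rmdn3 in 13 of 25, Scg5 in 11 of 25, 1442514_a_at in 11 of 24 and Nr5a2 in 9 of 25. In the NT4 knockout Slc6a2 passed in 16 of 25 and 1441692_at in 7 of 23. As differences between the knockouts, Bloc1s6 passed in 21 of 23, 1446755_at in 11 of 23, Slc6a2 in 9 of 24, Bdnf in 7 of 22 and 1441692_at in 4 of 22. The 10 probe sets named for the largest wild-type differences passed in every alternative that gave them a value. Dim probe sets and those not chosen for a gene have no value with the dimmer 50% left out or with 1 probe set per gene. Array signal also limits what can be seen, since 5.87% to 7.91% of probe sets per array read under 20. In simulated data, with changes only in probe sets brighter than the median, the knockout contrasts found 56% of 2-fold changes. The difference found 24%. These shares do not cover dim probe sets and may be too high for the real contrasts, which made fewer calls.

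Counts of probe sets are given for BDNF, NT4 and their difference, which were 8, 2 and 5. They were 5, 1 and 3 with centred arrays, 4, 0 and 1 with the sex-linked covariate, 4, 1 and 1 with 1 probe set per gene, and 4, 0 and 1 without both arrays of high Xist. With an unadjusted p under 0.05 and a fold of at least 1.5 they were 1562, 1118 and 1948. NT4 had 1 with the trend and robust estimation, and with the dimmer 50% left out NT4 had 1 and the difference 3. With only the 6 arrays of a line limma made 0 and 0 calls (2465 and 2972 at an unadjusted p under 0.05). With the replicate block it made 0, 0 and 0 (2986, 2496 and 2672 unadjusted). Replicate numbers do not pair the arrays, as the deviations of same-numbered arrays correlated at −0.16 to 0.10. For the wild types the count of 6275 became 2716 with the dimmer 50% left out, 2497 of them shared, and 2679 with 1 probe set per gene, 2477 of them shared.

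Lists past camera's threshold numbered 0 for BDNF, 9 for NT4, 2 for the difference and 0 for the wild types (4, 9, 7 and 4 at an unadjusted p under 0.05). BDNF had 3 with the trend, 2 with the sex-linked covariate, and 1 each with array weights, the median over probe sets, an offset of 50 and without both arrays of high Xist. NT4 had 5 with quantile normalization and 5 without both arrays of high Xist, the difference 5 with the trend or array weights and 1 with quantile normalization or the median over probe sets, and the wild types 1 without both arrays of high Xist. With an estimated correlation camera passed 0 for NT4 and 0 for the difference (2 and 0 at an unadjusted p under 0.05), and fry passed 0 and 0 (3 and 0 unadjusted) and 8 for the wild types. In either direction fry passed 1 for the difference with quantile normalization, and without both arrays of high Xist 1 for BDNF and 0 for NT4.

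Leaving out each array in turn gave 4 to 10 probe sets for BDNF, 0 to 5 for NT4, 1 to 4 for the difference and 4909 to 6440 for the wild types. Lists numbered 0 to 4 for BDNF, 4 to 9 for NT4, 1 to 6 for the difference and 0 to 1 for the wild types, and in either direction 2 to 5, 0 to 6, 0 to 1 and 22 to 26. BDNF lists numbered 4 without BDNF knockout replicate 3, 2 without BDNF knockout replicate 1 or 2 or NT4 wild-type replicate 3, and 1 without BDNF wild-type replicate 2 or NT4 knockout replicate 3. In either direction BDNF had 2 without BDNF wild-type replicate 2 or BDNF knockout replicate 3. NT4 had 6 without NT4 wild-type replicate 3, 2 without BDNF knockout replicate 3, and 0 without BDNF wild-type replicate 1, 2 or 3, NT4 wild-type replicate 2 or NT4 knockout replicate 2. The difference had 1 without BDNF knockout replicate 2 or 3. The correlation of the knockout effects ranged from −0.00528 (without BDNF wild-type replicate 1) to 0.120. Directions turned over ranges of −0.035 to 0.54 for Gfra2, −0.089 to 0.52 for Aurka and −0.54 to 0.036 for Kif20a in the BDNF knockout, and of −0.21 to 0.016 for Ntf5 and −0.087 to 0.0013 for Ngfr in the NT4 knockout. None of these was called.

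Other reversals were Ntf5 at 0.025 with array weights, and Gfra2 at −0.035, Aurka at −0.089 and Scg5 between the wild types at −0.033 without both arrays of high Xist. With array weights 204 of the named values kept their direction and side of the threshold, 202 with the trend, 201 with quantile normalization, 202 with centred arrays, 205 and 203 with offsets of 16 and 50, 197 with the sex-linked covariate, 186 with the replicate block and 182 without both arrays of high Xist. At a fold of at least 2 the authors' tables hold 67 probe sets for BDNF and 51 for NT4, with 1 on both. The gene lists were not run with the dimmer 50% left out, 1 probe set per gene, the unadjusted threshold or only 6 arrays, and with centred arrays only their means and camera calls were computed.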

Other observations

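The tests of the array medians, of Bdnf neighbours by their median t and of Ntf5 neighbours by a count were chosen only after the results were seen, and the genes named here were picked after their values were seen.

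Single members of lists that did not pass had low unadjusted p-values, while their lists held members on both sides. In the BDNF knockout 12 of the ion channel genes were higher and 13 lower (fry in either direction, adjusted p = 0.888), and 9 of the immediate early genes were higher and 9 lower (0.637). Kcnd2, a subunit of potassium channels that open below the firing threshold, differed by −2.62 (SE 0.69, adjusted p = 0.453). It went from 113 in the wild type to a dim 15.4 in the knockout (n = 3 each), so only its direction is read. Over the alternatives its adjusted p ran from 0.115 to 0.861. Vgf, a neuropeptide precursor induced by neurotrophins, stood at −0.46 (SE 0.17) with the loss of BDNF, from 2145 to 1566, and at −0.39 (SE 0.17) with the loss of NT4, from 1840 to 1423. The immediate early gene Ier2 differed by −0.43 (SE 0.14), the ephrin gene Efna2 by −0.48 (SE 0.15) and its receptor family member Epha7 by 0.53 (SE 0.17) in the BDNF knockout. In the NT4 knockout the neuropeptide genes Tac1 and Gal differed by −0.35 (SE 0.10) and 0.54 (SE 0.23), and the semaphorin receptor gene Nrp2 by 0.43 (SE 0.13). None of these passed over all genes, and their direction was the same in each alternative that gave them a value.

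The NT4 knockout arrays had a higher median intensity than the wild-type arrays of the line, 190 ± 9.10 against 176 ± 6.2 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). In the BDNF line the medians were 172 ± 5.33 and 173 ± 4.54 (exact two-sided permutation p = 0.6).

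Genes beside Ntf5 were tested for a segment of another strain carried with the targeted allele. Here too the windows elsewhere were drawn at random and overlap, so their permutation p-values only rank a window. The median absolute moderated t of the 400 measured genes around Ntf5 was 0.913, against a median of 0.987 and a 95th percentile of 1.06 for windows elsewhere (one-sided permutation p = 0.908). By this measure the genes around Bdnf stood at 1.13 in the BDNF knockout, above the 95th percentile of 1.09 (one-sided permutation p = 0.007). A count points the other way for Ntf5: limma called 0 genes in its window, but 8 had a p under 0.01 (adjusted over the probe sets of a gene alone), against a median of 4 and a 95th percentile of 7 elsewhere (one-sided permutation p = 0.0174). A segment that fills part of the window need not move a median over all of it, so such a segment stays open. Lin7b, which stood at −1.07 in the NT4 knockout without passing, lies 3 measured genes from Ntf5.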
